A study of Homo sapiens with 8 samples.

How the data were processed

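Gene expression was measured on 8 Affymetrix arrays in MM1.S, an established human multiple myeloma cell line. Per the labels, clones had been made with a CRISPR-Cas9 vector, sorted for GFP, and tested for FOXO3 protein by Western blot. There were 2 control clones that had received Cas9 only and 2 FOXO3 knockout (KO) clones. Each clone was measured once untreated and once after overnight treatment with 2.5 µM MK2206, an inhibitor of the kinase AKT. This gave 4 groups of 2 arrays: untreated control, MK2206-treated control, untreated FOXO3 KO and MK2206-treated FOXO3 KO. Replicate 1 and replicate 2 of each group are clone 1 and clone 2 of that genotype. Per the labels' protocols, total RNA was made into biotin-labelled complementary RNA with a one-cycle kit.

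The deposited values are log2 signals, 1 per probe set and array, in a single table of 54675 probe sets. The submitters' processing notes name MAS5 and GCOS, the Affymetrix software that scales each array to a common mean signal. Its version and settings are not given in the sources used here. The values themselves showed that the linear signals of every array had the same 2% trimmed mean, 100, and that between 4.72% and 6.88% of the values per array lay at 0, the log2 of a linear floor of 1. Detection calls were not used here, so a value near the floor cannot be told from no signal. The authors' scaling holds the mean signal of each array fixed, so a change in the total amount of messenger RNA per cell would not appear in these values.

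The deposited log2 values were used as they stand, with no further normalization and no pseudocount. Of the probe sets, 62 are control probe sets and were left out of the tests. In the platform annotation, 41097 probe sets had 1 gene symbol, 1801 had several and 11721 had none listed, and symbols were updated through gene identifiers for 41043. Probe sets with several symbols or none were left out. The 19775 named genes were each represented by the probe set with the highest mean over the 8 arrays. A gene was tested if that mean reached the median of all probe sets that are not controls, 4.07 on the log2 scale or 16.7 in linear signal, which left 11647 genes.

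All 8 arrays entered one limma fit (version 3.58.1 in R 4.3.3) of the 4 group means, with lmFit and eBayes, 4 residual degrees of freedom and 2.73 prior degrees of freedom. From it came 6 comparisons: MK2206 against untreated in control clones, in FOXO3 KO clones and averaged over all 4 clones, the difference between the KO and the control response (the interaction), and KO against control among untreated and among treated arrays. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p below 0.05 were called. Whether the genes called over all 4 clones responded less in KO clones was read from their interaction estimates, because the averaged effect and the interaction are independent contrasts when groups are equal in size.

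There were 21 gene lists: FOXO targets, G1/S and DNA replication, G2/M and mitosis, ribosome biogenesis and MYC targets, ATF4 and amino acid response, glycolysis and hypoxia, ER chaperones and unfolded protein response, growth factor receptor and PI3K pathway, BCL2 family, autophagy and lysosome, p53 targets, interferon response, NF-kB targets, immediate-early genes, cholesterol synthesis and SREBP2 targets, fatty acid synthesis, plasma cell identity, B cell identity, and markers of T cells, of myeloid cells and of stromal and epithelial cells. Lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, were run as alternatives. With an estimated correlation camera also rests on the 4 residual degrees of freedom. A call lost by it therefore does not measure the correlation between genes alone. Members passing after adjustment over the list alone were counted beside those passing over all genes. Some genes stand on several lists, so the lists are not independent. The FOXO target list shares RICTOR, PIK3IP1, IRS2, INSR and ERBB3 with the growth factor receptor and PI3K pathway list. It also shares GABARAPL1 with the autophagy list, BCL2L11 with the BCL2 family, BCL6 with B cell identity, and TP53INP1 and SESN1 with p53 targets.

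The groups, lists, tests, filters and alternatives, and the rule for naming genes, were chosen before the data were examined, except where stated. For each comparison the rule took the 8 genes with the largest rise and the 8 with the largest fall among called genes whose arrays did not overlap between groups. Where no gene was called, it took the 5 with the smallest p. From each list it allowed up to 4 members with the smallest p, and it always took FOXO3, FOXO1, FOXO4, AKT1 and AKT2. FOXO4 lay below the filter and was not tested. Some items that were looked at are not reported here.

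The treated and the untreated array of one clone form a pair, since the labels give the clone of each sample. Deviations from the group means correlated across genes between the arrays of one clone, with a correlation of 0.323 in control clones and 0.354 in KO clones. Fits with the clone as a fixed or a random block were alternatives. Other alternatives were quantile normalization, centring each array on its median, adding 1 or 64 to the linear signal before log2, no filter or a filter at the 75th percentile, testing all named probe sets, eBayes with trend and robust, only the arrays of the groups compared, a minimum change of 2-fold, and leaving out each array and each clone in turn. Scaling each array on its 24 poly-A control probe sets or its 18 hybridisation control probe sets was added after the data were seen. The poly-A controls are bacterial transcripts added to the RNA before labelling, and the hybridisation controls are labelled transcripts added just before hybridisation.

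The code was tested on simulated data in which 100 of the 11647 genes were changed 2-fold and 100 were changed 4-fold. The 4-fold changes were recovered for between 86 and 99 of each 100 in the 6 comparisons. The 2-fold changes were recovered for 62 of 100 in control clones, 57 in KO clones, 92 over all 4 clones, 9 for the interaction, 59 for untreated KO against control and 58 for treated KO against control. Between 3.61% and 5.0% of the simulated calls were false. The number of arrays limits the precision of every value. No pair of arrays was a duplicate: at most 0.837% of values above the floor were identical between 2 arrays. Figures were drawn with Python 3.11.15.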

Results

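Transcript levels were measured in MM1.S multiple myeloma cells to ask how the response to AKT inhibition depends on FOXO3. FOXO3 is a transcription factor of the forkhead family that is held out of the nucleus when AKT phosphorylates it. The 8 arrays comprised 2 Cas9-only control clones and 2 FOXO3 KO clones, each untreated and after overnight MK2206. All 8 arrays had the same trimmed mean signal, 100, and pairwise rank correlations between 0.904 and 0.951 over all probe sets. The log2 difference between the 3′ and 5′ control probe sets of ACTB, a measure of RNA integrity, averaged 0.39 ± 0.12 in untreated control, 0.56 ± 0.06 in treated control, 0.23 ± 0.03 in untreated KO and 0.16 ± 0.07 in treated KO arrays (SD, n = 2 each). That of GAPDH averaged -0.178, -0.245, -0.168 and -0.117 in the same order, lowest in treated control, where that of ACTB was highest. Each clone was measured once per treatment and the labels do not state separate cultures, so p-values measure only the spread between these samples, which may be technical in part.

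The control transcripts added in the laboratory were not level between arrays. From the untreated to the treated array of a clone, the median poly-A control rose by 0.96 in control clone 1, 0.84 in control clone 2, 0.19 in KO clone 1 and 0.05 in KO clone 2 on the log2 scale. Scaling on these controls would shift every gene's change by -0.84 in control clones and -0.17 in KO clones, and scaling on the hybridisation controls by -0.51 and -0.07. The shifts are -0.50 and -0.29 over all clones, 0.67 and 0.43 for the difference in response, 0.34 and -0.32 for untreated KO against control, and 1.01 and 0.11 for treated KO against control. All changes below are relative to the deposited scaling, and a change of the opposite sign that is smaller than its comparison's shift turns under that scaling.

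In the probe sets that name FOXO3 alone, the group means read lower in the KO clones under the deposited scaling, but the transcript was not absent. The probe set with the highest signal, which stands for the gene, read 11.39 ± 0.04 in untreated control, 11.87 ± 0.19 in treated control, 11.13 ± 0.415 in untreated KO and 11.26 ± 0.37 in treated KO arrays (log2 mean ± SD, n = 2 each). The KO clones differed from control by -0.26 untreated and -0.61 treated, with adjusted p = 0.617 and 0.102. Both differences turn positive with scaling on the poly-A controls. In the other 3 FOXO3 probe sets the difference lay between -0.89 and -1.59 untreated and was -1.29, -1.23 and -1.96 treated, with both KO arrays below both control arrays in each. Values adjusted over all probe sets, here and below, or over the named probe sets come from separate fits. Each of these has its own eBayes estimate of the spread. Adjusted over all probe sets of the array none of the 4 passed, the smallest adjusted p being 0.447 untreated and 0.0579 treated. Among them 2 passed among treated arrays when adjusted over the named probe sets above the filter (-1.23 with adjusted p = 0.0093 and -1.96 with adjusted p = 0.01). KO clone 2 lay below KO clone 1 in every case. In the brightest probe set untreated KO clone 1 read 11.42, against 11.36 and 11.41 in the untreated control arrays. Probe sets that name both FOXO3 and FOXO3B, not tested at the gene level, differed by -0.734, -0.818 and -0.455 untreated and by -1.07, -0.919 and 0.448 treated. In the last of these KO clone 1 lay above the control mean, by 0.777 untreated and 1.47 treated. The position of the edit is not given in the sources used here, and a frameshift can leave the transcript in place, so these levels do not test the knockout of the protein.

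**Figure D1:**
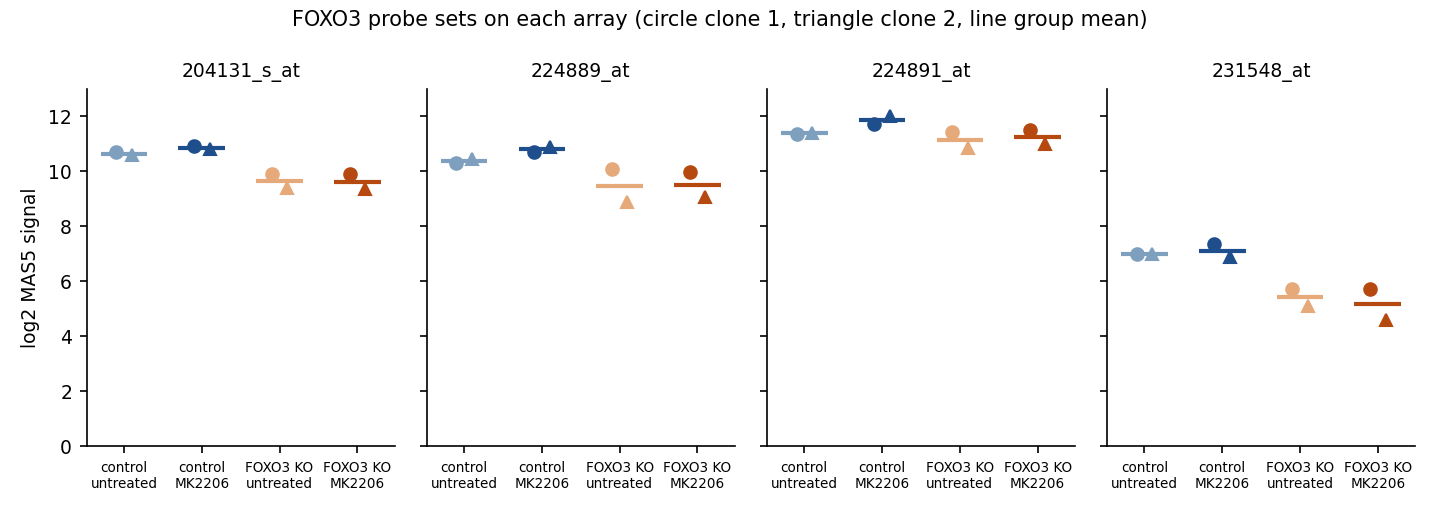
Log2 signal of the 4 probe sets that name FOXO3 alone on each of the 8 arrays, with circles for clone 1, triangles for clone 2 and lines for the group means (n = 2). The KO arrays lie below the control arrays in 3 of the probe sets, and the brightest probe set differs least, by -0.26 untreated and -0.61 treated.

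The other members of this pathway changed little in most comparisons. FOXO1, a close relative of FOXO3, rose by 0.74 ± 0.17 (SE) with MK2206 in control clones (adjusted p = 0.0192). In the separate fit of all probe sets its SE was 0.205, with adjusted p = 0.114. FOXO1 did not pass in KO clones (-0.30, adjusted p = 1), and its response differed between the genotypes by -1.04 (adjusted p = 0.0482). That difference lost the call in each of the 8 fits that left out 1 array (adjusted p between 0.0608 and 0.14) and when adjusted over all probe sets (adjusted p = 0.24). For the same difference a dimmer FOXO1 probe set, below the filter, read 2.98, the opposite sign, and another read -0.74. Neither passed when adjusted over all probe sets (adjusted p = 0.279 and 0.712). The rise of 0.74 in control clones, from the probe set that stands for FOXO1, lost the call without either array of the untreated group or without treated replicate 2. This rise changes sign under scaling on the poly-A controls. FOXO3 itself read 0.48 in control clones (adjusted p = 0.19, or 0.0299 with the clone as a fixed block) and 0.30 over all clones (adjusted p = 0.269, or 0.0485 with that block). Both values turn negative with scaling on the poly-A controls, the first also on the hybridisation controls. AKT1 was higher in treated KO than in treated control arrays, by 1.19 ± 0.23 (adjusted p = 0.00831, or 0.0579 adjusted over all probe sets), and by 0.88 among untreated arrays without passing (adjusted p = 0.247). AKT1 did not pass for MK2206 in control clones (-0.47, adjusted p = 0.159), in KO clones (-0.16, adjusted p = 1) or over all clones (-0.32, adjusted p = 0.208), and AKT2 passed in none of the 6 comparisons.

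In control clones, MK2206 raised genes of the FOXO program and lowered the genes of DNA replication and mitosis. FBXO32, the muscle ubiquitin ligase subunit atrogin-1 and a classical FOXO target, rose by 3.52 ± 0.23 (SE) or 11.5-fold (adjusted p = 0.000494), from 5.62 to 9.14 in mean log2 signal. PIK3IP1, an inhibitor of PI3K, rose by 2.68 ± 0.29 (adjusted p = 0.00141), and BCL2L11, which encodes the death-inducing BCL2 relative BIM, by 1.55 ± 0.13 (adjusted p = 0.000737). CDC45, a subunit of the replicative helicase, fell by 6.04 ± 0.33 (adjusted p = 0.000342), and UHRF1, which maintains DNA methylation at replication, fell by 5.20 ± 0.23 (adjusted p = 0.00032). For these genes, and for each gene called in this comparison, both treated arrays lay on one side of both untreated arrays.

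The other genes with the largest rises were PLAAT4, a phospholipase and acyltransferase (3.62), CBLB, a ubiquitin ligase (3.41), RASSF6 (3.31), the histone genes H2AC6 (3.15) and H2AC14 (3.05), YPEL2 (2.91) and LRRC2 (2.85), with adjusted p between 0.00116 and 0.0115. The largest falls besides CDC45 and UHRF1 were those of IMPA2, an inositol monophosphatase (-6.11), SHTN1 (-5.77), HES6, a basic helix-loop-helix factor (-5.73), MYCN (-5.05), CHAF1B, a chromatin assembly subunit (-4.55), and GINS2, another part of the replicative helicase (-4.46), with adjusted p between 0.000376 and 0.00516. IMPA2, CDC45, SHTN1 and MYCN fell to mean signals between 0.57 and 0.89, close to the floor of 0, so the size of their change is set by dim values. HES6, CHAF1B and GINS2 also fell below the filter, and CBLB, LRRC2 and H2AC14 rose from below it. CBLB lost the call without treated replicate 1 (adjusted p = 0.0533) or untreated replicate 2 (adjusted p = 0.0625).

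Nearly the whole of both cell cycle lists fell in control clones. Of 32 tested G1/S and DNA replication genes, 31 fell and 1 did not pass, with a median of -2.42, among them MCM4 (-3.20, adjusted p = 0.00032) and RFC3 (-2.27, adjusted p = 0.000342), a helicase subunit and a subunit of the PCNA clamp loader. All 33 G2/M and mitosis genes fell, with a median of -1.62, among them the mitotic kinesin KIF23 (-2.53), the cytokinesis scaffold ANLN (-2.78) and the kinetochore subunit NDC80 (-1.71). The same counts passed when adjusted over the list alone. The list tests gave adjusted p = 2.32e-18 and 1.99e-16, or adjusted p = 0.259 and 0.265 with an estimated correlation, and both lists fell by fry (adjusted p = 0.0026 each).

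Biosynthetic lists were also lower in treated control clones. In the ATF4 and amino acid response list 11 of 28 fell, 1 rose and 16 did not pass (15 fell and 2 rose when adjusted over the list alone), with a median of -0.47, including PSAT1 of serine synthesis (-2.32, adjusted p = 0.000603) and ALDH1L2 of mitochondrial folate metabolism (-3.04, adjusted p = 0.00161). In the glycolysis and hypoxia list 13 of 23 fell, 1 rose and 9 did not pass (13 and 1 adjusted over the list alone), with a median of -0.62, including PKM (-2.31), ENO2 (-3.86) and VEGFA (-1.08). In the ribosome biogenesis and MYC target list 10 of 27 fell and 17 did not pass (17 fell and 1 rose when adjusted over the list alone), with a median of -0.47, including LYAR (-1.77) and CAD of pyrimidine synthesis (-1.27). The list tests gave adjusted p = 0.00444, 0.0104 and 0.00137, and adjusted p = 0.217, 0.325 and 0.293 with an estimated correlation.

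The FOXO target list rose most. Of 28 tested members 20 rose, 1 fell and 7 did not pass (21 rose and 2 fell when adjusted over the list alone), with a median of 1.33 (adjusted p = 3.52e-09, or adjusted p = 0.217 with an estimated correlation). FBXO32, PIK3IP1, BCL2L11 and TP53INP1, a stress-induced p53 target (1.52, adjusted p = 0.000733), were among them. The rise kept its sign under both control scalings, with medians of 0.49 on the poly-A and 0.82 on the hybridisation controls.

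Smaller rises were found in signalling, secretory and lineage lists, and each of these medians turns negative under both control scalings. In the growth factor receptor and PI3K pathway list 8 of 23 rose, 2 fell and 13 did not pass (11 and 2 adjusted over the list alone), including RICTOR of mTORC2 (1.49) and the interleukin 6 coreceptor IL6ST (1.03). In the ER chaperone and unfolded protein response list 8 of 24 rose, 2 fell and 14 did not pass (10 and 2), including ERN1 (1.65) and XBP1 (0.91). In the autophagy and lysosome list 7 of 25 rose, 2 fell and 16 did not pass (7 and 2), including GABARAPL1 (2.70) and MAP1LC3B (0.95). RICTOR and GABARAPL1 are also on the FOXO target list. Among plasma cell identity genes 10 of 25 rose, 4 fell and 11 did not pass (10 and 4), with MAF (0.92) and CADM1 (1.07) higher and ITGA4 (-1.22) lower. The medians were 0.45, 0.35, 0.29 and 0.32. The list tests gave adjusted p = 0.000437, 0.00137, 0.00384 and 0.00569, and adjusted p = 0.217, 0.285, 0.293 and 0.281 with an estimated correlation.

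Among NF-kB targets 7 of 14 rose and 7 did not pass (7 adjusted over the list alone), including the receptor CD40 (1.81, adjusted p = 0.00288). Among immediate-early genes 5 of 13 rose, 1 fell and 7 did not pass (5 and 1), with the phosphatase DUSP1 higher (2.00, adjusted p = 0.000737) and PHLDA1 lower (-2.14, adjusted p = 0.00208), although another probe set of each gave the opposite sign, -0.28 for DUSP1 and 0.68 for PHLDA1, neither passing. The medians of these lists, 0.38 and 0.42, also turn negative under both control scalings. Their list tests gave adjusted p = 0.0129 and 0.0104, and adjusted p = 0.217 for both with an estimated correlation.

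The remaining lists did not pass in control clones. In the BCL2 family 5 of 13 members rose and 1 fell, with BCL2 higher (1.86, adjusted p = 0.00191) and PMAIP1, which encodes NOXA, lower (-1.27, adjusted p = 0.00325), and the list test gave adjusted p = 0.117. Of p53 targets 3 of 19 rose and 2 fell (3 and 4 adjusted over the list alone), with DDB2 lower (-1.67), and of interferon response genes 5 of 20 rose and 1 fell (8 and 2), with OAS1 (1.86) and IRF7 (1.03) higher (list adjusted p = 0.535 and 0.142). In the cholesterol list 2 of 17 rose and 2 fell, with the sterol isomerase EBP lower (-1.06), and in the fatty acid list 1 of 9 rose (none adjusted over the list alone), with list adjusted p = 0.403 and 0.619. The medians of these 5 lists, between 0.00 and 0.30, turn negative under both control scalings. Of B cell identity genes 2 of 15 rose and 1 fell, the repressors BACH2 (1.91) and BCL6 (2.05) being higher, while the list median was -0.05, its mean 0.17 and its test positive in sign (adjusted p = 0.657). No stromal or epithelial marker passed among 6 tested (adjusted p = 0.784 for the list), SPARC reading -1.91 (adjusted p = 0.0734, or 0.0115 and 0.00405 with the clone as a random and a fixed block), and none of the 2 T cell or 4 myeloid markers tested passed.

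Over all genes, MK2206 changed 3696 of 11647 tested genes in control clones, 1489 higher and 2207 lower, against 5157 at an unadjusted p below 0.05 and 582 by chance at that threshold. All 3696 had arrays that did not overlap between treated and untreated, which a call with 2 arrays against 2 nearly requires. The 33.3% that chance gives for genes not chosen by their test is no measure for them. A change of at least 2-fold was reached by 561 of the higher and 1067 of the lower genes. Higher genes made up 40.3% of the calls under the deposited scaling, but 2.72% of 8065 calls were higher with scaling on the poly-A controls and 7.27% of 5599 with scaling on the hybridisation controls. Without the filter on dim genes 2062 passed. Leaving out untreated replicate 1 left 2032 calls and leaving out untreated replicate 2 left 1906, with the lone remaining array assumed to vary like those of the other groups.

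In FOXO3 KO clones the same treatment gave no called gene. FBXO32 differed by 0.78 ± 0.23 (SE, adjusted p = 1) and BCL2L11 by 0.41 ± 0.13 (adjusted p = 1). MCM4 differed by -0.34 and KIF23 by -0.32, both with adjusted p = 1. The 5 genes with the smallest p, none of them passing, were UTS2R (-1.92), ACSF3 (1.13), CCDC141 (1.06), ATP2B4 (-0.89) and RGS1, a regulator of G protein signalling (0.98), each with adjusted p = 0.765. In UTS2R, ACSF3 and CCDC141, at least 1 group mean lay below the expression filter.

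By limma, 0 of 11647 genes passed in KO clones and 441 had an unadjusted p below 0.05, where chance gives 582. Of the other ways of processing, 14 also gave 0. Leaving out treated KO replicate 2 gave 3 calls, all lower, and leaving out each other KO array gave 0, with the lone array assumed to vary like the other groups. On simulated data the same test recovered 57 of 100 genes changed 2-fold and 96 of 100 changed 4-fold when all of these were changed at once, which does not show that a large change of a single gene would pass.

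Small shifts of whole lists were called in KO clones by camera, although no single member passed. The G2/M and mitosis list lay lower in 33 of 33 members (median -0.22, adjusted p = 4.51e-07) and G1/S and DNA replication in 31 of 32 (median -0.12, adjusted p = 0.00325). Higher were the cholesterol (0.18), fatty acid (0.14), ER chaperone (0.16), autophagy (0.17) and interferon response (0.17) lists, with adjusted p between 0.00274 and 0.0279. Examples, none passing, were SC5D (0.24), SQLE (0.32), SCD (0.25), HERPUD1 (0.38), CTSB (0.40), ISG15 (1.16) and IFI6 (0.78). All 7 list calls were lost with an estimated correlation, with adjusted p = 0.488 for the 5 higher lists, 0.547 for G2/M and 0.648 for G1/S, and fry called none of them (adjusted p between 0.503 and 0.736). With the clone as a fixed block the fatty acid list lost its call by camera (adjusted p = 0.0801). The fatty acid and ER chaperone medians turn negative with scaling on the poly-A controls. The other 12 lists did not pass, the FOXO target list among them (median 0.15, adjusted p = 0.143).

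The response to MK2206 itself differed between the genotypes. FBXO32 rose by 2.75 ± 0.33 (SE) less in KO than in control clones on the log2 scale (-2.75, adjusted p = 0.0103), PINK1, a kinase of mitophagy, by -2.95 (adjusted p = 0.0107), and BCL2L11 by -1.15 (adjusted p = 0.0177). The replication genes CDC45, UHRF1 and MCM4 fell less in KO clones, with differences of 6.02 ± 0.46, 4.93 ± 0.33 and 2.86 ± 0.20 (adjusted p = 0.00512, 0.0048 and 0.00486). For these genes, and each gene called for this difference, both KO clones' own changes lay on one side of both control clones' own changes.

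**Figure D2:**
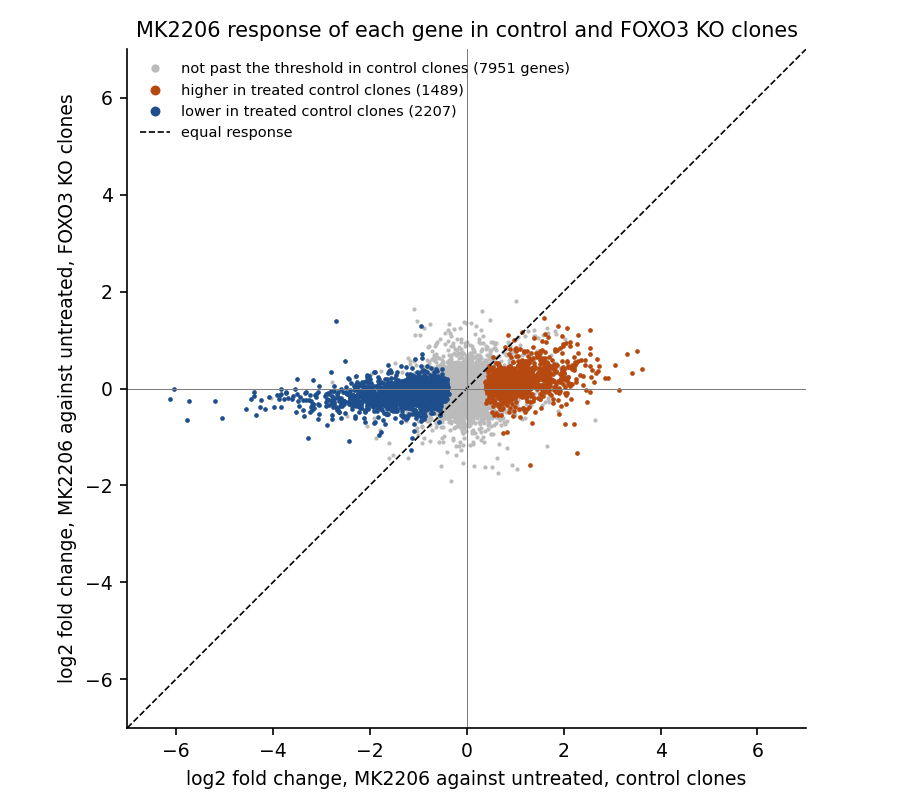
Log2 fold change with MK2206 of each of 11647 tested genes in FOXO3 KO clones (vertical) against control clones (horizontal), each from 2 treated and 2 untreated arrays; coloured points passed the test in control clones (1489 higher, 2207 lower) and the dashed line marks an equal response. The points lie along the horizontal axis, and the SD of the change over all genes is 0.79 in control and 0.26 in KO clones.

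Besides these, the largest positive differences were those of IMPA2 (5.89), HES6 (5.47), SHTN1 (5.12), MYCN (4.45), the ubiquitin ligase adaptor DTL (4.32) and the ribonucleotide reductase subunit RRM2 (4.25), with adjusted p between 0.0048 and 0.0154. The largest negative ones were those of the matricellular gene CCN2 (-3.60), PLAAT4 (-3.22), H2AC6 (-3.18), the noncoding LOC101926984 (-2.88), PROX1 (-2.75) and LRRC2 (-2.64), with adjusted p between 0.0102 and 0.0439. CDC45, IMPA2, HES6, SHTN1 and MYCN lay below the filter in treated control clones, CCN2 in treated KO clones, PROX1 in both KO groups and LRRC2 in all groups but treated control, so the size and order of their differences are set by dim values.

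By list, the difference was positive for 28 of 32 G1/S and DNA replication genes and 27 of 33 G2/M and mitosis genes, with none negative (31 and 32 adjusted over the list alone) and medians of 2.36 and 1.40, including TYMS (3.39), KIF23 (2.21) and ANLN (2.48). It was negative for 14 and positive for 1 of 28 FOXO targets (18 and 1), with a median of -1.22, including TP53INP1 (-1.19). The list tests gave adjusted p = 3.34e-22, 2.7e-17 and 3.75e-10, and adjusted p = 0.241, 0.249 and 0.233 with an estimated correlation.

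Of 28 ATF4 and amino acid genes 3 had a positive difference (9 adjusted over the list alone), PSAT1 (1.98) among them, as had 4 of 23 glycolysis genes (7) and 2 of 27 ribosome biogenesis genes (2), with medians of 0.52, 0.53 and 0.42. In the growth factor receptor and PI3K pathway list 3 of 23 had a negative difference (4), with RICTOR at -1.30 and PIK3IP1 at -2.08. Both genes are also on the FOXO target list, so the pathway list partly repeats that list. In the autophagy list 3 of 25 were negative and 1 positive (4 and 1). In the immediate-early and plasma cell lists 1 was negative and 1 positive of 13 and 25 (1 and 1, and none), and in the ER chaperone and NF-kB target lists 1 was negative of 24 and 14 (none, and 1). The medians of these 6 lists were -0.43, -0.18, -0.64, -0.38, -0.30 and -0.27. These 9 lists had adjusted p between 0.000622 and 0.0435, and adjusted p between 0.233 and 0.415 with an estimated correlation, and NF-kB targets lost the call with the clone as a fixed block (adjusted p = 0.0766). Fry did not call the ER chaperone (adjusted p = 0.102), autophagy (0.301), NF-kB target (0.0531) and plasma cell (0.0531) lists. The negative medians of these 6 lists turn positive with scaling on the poly-A controls, and those of all but the immediate-early genes with scaling on the hybridisation controls. The other 7 lists did not pass. Of their members 2 of 15 B cell identity genes were negative, BACH2 (-2.01, adjusted p = 0.0173) among them, 2 of 17 cholesterol genes were positive, 2 of 13 BCL2 family genes were negative and 1 positive (5 and 1), and 1 of 19 p53 targets was negative and 1 positive.

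**Figure D3:**
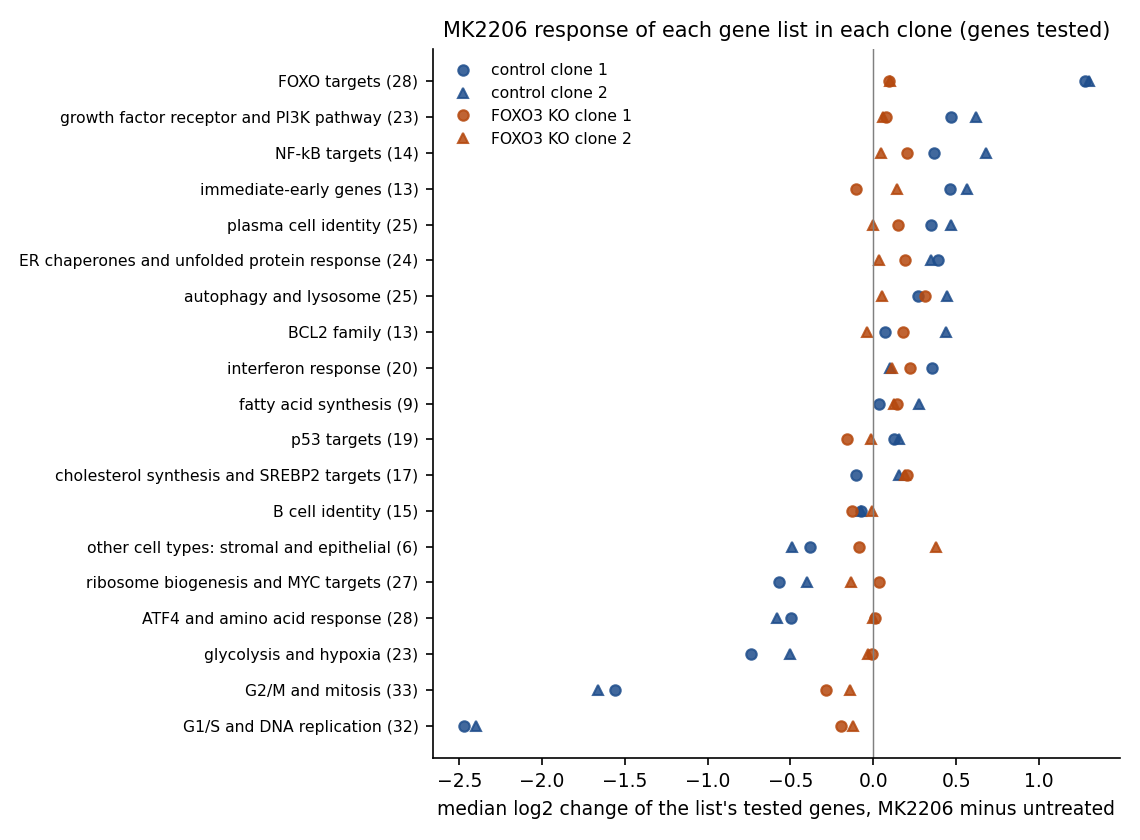
Median log2 change with MK2206 (treated minus untreated array) of the tested genes of each list in each of the 4 clones, with blue for control and orange for FOXO3 KO clones, and the number of tested genes in parentheses. The G1/S list lies at -2.47 and -2.40 in the control clones against -0.20 and -0.12 in the KO clones, and the FOXO target list at 1.28 and 1.30 against 0.09 and 0.10.

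The difference in response passed for 1057 genes, 771 positive and 286 negative, against 3157 at an unadjusted p below 0.05. For each of the 1057 the clones of the genotypes did not overlap, which such a call nearly requires (chance gives 33.3% for genes not chosen by their test). With the clone as a block the count was 2072 (1337 and 735) for a fixed and 2834 for a random block. Without the filter on dim genes it was 34, and 7 of the 27 called genes named here passed. That setting adds genes to adjust over and also refits eBayes with the dim genes, so the loss is not from the adjustment alone. Positive differences made up 72.9% of the calls, 97.7% of 3608 with scaling on the poly-A controls and 95.4% of 1973 with scaling on the hybridisation controls. The count depended on single arrays: it was 77 without untreated control replicate 1, 120 without untreated control replicate 2, 627 and 583 without treated control replicates 1 and 2, 132 and 424 without untreated KO replicates 1 and 2, 148 without treated KO replicate 2, and 0 without any whole clone, the lone array being assumed to vary like the other groups. Of the 27 called genes named here, 9 passed without untreated control replicate 1, and between 15 and 24 without each other array. CDC45, IMPA2, UHRF1, DTL, RRM2, MCM4, TYMS, KIF23 and ANLN passed in each of the 8 fits that left out 1 array.

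Averaged over all 4 clones, MK2206 changed many of the same kinds of genes. The average contains the arrays of the control clones, so this likeness is partly built in and is not a separate result. Among called genes that moved the same way in all 4 clones, the largest rises were those of FBXO32 (2.15 ± 0.16, adjusted p = 0.00178), RASSF6 (2.01), PLAAT4 (2.00), the phosphodiesterase PDE4B (1.88), SSPN (1.69), the integrin ITGB8 (1.66), PIK3IP1 (1.65) and the noncoding LINC-PINT (1.63). Among the same genes the largest falls were those of SHTN1 (-3.21 ± 0.30, adjusted p = 0.00271), IMPA2 (-3.17), HES6 (-3.00), MYCN (-2.82), UHRF1 (-2.73), CHAF1B (-2.49), ketohexokinase KHK (-2.45) and GINS2 (-2.33). The adjusted p lay between 0.00178 and 0.0233, and SHTN1, IMPA2, HES6, MYCN, CHAF1B, KHK and GINS2 lay below the filter in treated control clones, so the size of their fall is set by dim values. RASSF6 and PLAAT4 lost the call without untreated control replicate 1 (adjusted p = 0.0554 and 0.051), and GINS2 without 1 of 5 arrays: untreated control replicate 1 (0.0689) or 2 (0.0707), untreated KO replicate 1 (0.0504) or 2 (0.075), or treated KO replicate 1 (0.0749).

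Over all clones 33 of 33 G2/M and mitosis genes and 30 of 32 G1/S and DNA replication genes fell (33 and 31 adjusted over the list alone), among them KIF23 (-1.43) and TYMS (-1.81), and 15 of 28 FOXO targets rose and 1 fell (18 and 1), among them BCL2L11 (0.98, adjusted p = 0.00271). Their list tests gave adjusted p = 1.85e-17, 2.85e-19 and 1.67e-08. A further 10 lists passed with adjusted p between 0.000516 and 0.0261. Lower were ribosome biogenesis (6 of 27 fell), ATF4 (7 of 28 fell, 1 rose) and glycolysis (5 of 23 fell, 1 rose). Higher were ER chaperones (5 of 24 rose), the growth factor and PI3K pathway (4 of 23), autophagy (6 of 25, 1 fell), interferon response (4 of 20, 1 fell), NF-kB targets (5 of 14), immediate-early genes (5 of 13, 1 fell) and plasma cell identity (5 of 25, 3 fell), OAS1 (1.33, adjusted p = 0.0119) being an interferon response gene that rose. Adjusted over the list alone, 6, 7 and 11 genes of the lower lists fell, and 7, 7, 7, 5, 7, 5 and 9 of the higher lists rose, in the same order. With an estimated correlation the 13 lists had adjusted p between 0.224 and 0.326, and the interferon response list lost its call with the clone as a fixed block (adjusted p = 0.0551). The medians of the 7 further higher lists turn negative with scaling on the poly-A controls, and those of NF-kB targets and immediate-early genes alone stay positive with scaling on the hybridisation controls.

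These averages hide unequal contributions of the genotypes. Of the 933 genes called as rising over all clones, 96.4% rose less in KO clones (fry, adjusted p = 0.000525), with a median change of 0.97 in control and 0.22 in KO clones. Of the 1467 called as falling, 98.2% fell less in KO clones (fry, adjusted p = 0.000268), with medians of -1.18 and -0.15. The interaction passed for 245 of the rising genes, 244 of them weaker in KO clones, and for 720 of the falling ones, 719 of them weaker. Simulated data without any interaction, in which genes varied independently of each other, gave 50.7%. That value checks the way the genes were chosen and does not give the spread to be met among clones. The choice favours genes whose arrays varied little, and fry used the same arrays to estimate that spread. The simulation did not check the fry p-values, which may therefore be too small.

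Over all clones 2400 genes were called, 933 higher and 1467 lower, against 4255 at an unadjusted p below 0.05. Of the 2400, 1755 moved the same way in all 4 clones. They were chosen by the averaged effect, so the 12.5% that chance gives for genes not so chosen is no measure for them. Higher genes made up 38.9% of the calls, 2.09% of 7083 with scaling on the poly-A controls and 6.97% of 4032 with scaling on the hybridisation controls, and the clone as a random block gave 4366 calls. Without the filter on dim genes 730 passed. Without 1 array the count was 1129 (untreated control replicate 1), 1085 (untreated control replicate 2), 1583 (treated control replicate 2), 1551 (untreated KO replicate 1), 1148 (untreated KO replicate 2) or 1074 (treated KO replicate 1). Without a whole clone it was 369 and 164 for control clones 1 and 2 and 450 and 761 for KO clones 1 and 2, the lone array being assumed to vary like the other groups. Of the 20 called genes named here 13, 11, 16 and 16 passed without these clones.

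Among untreated arrays no gene passed between FOXO3 KO and control clones. The 5 genes with the smallest p, none passing, were HLA-DRB1 (1.67 ± 0.15, SE) and LOXL4 (2.06 ± 0.21), higher in both KO arrays than in both control arrays, and DEPP1 (-3.67 ± 0.33), CX3CR1 (-1.47 ± 0.14) and CLIP4 (-1.46 ± 0.15), lower in both. HLA-DRB1 encodes an antigen-presenting MHC class II chain, DEPP1 is induced by FOXO factors, CX3CR1 is a chemokine receptor and LOXL4 a lysyl oxidase. Their adjusted p was 0.0776, and 0.0905 for CLIP4. DEPP1 lay below the filter in the KO arrays, so the size of its difference rests on a signal that cannot be told from none. The MHC class II gene HLA-DRA and its chaperone CD74 read 1.03 (adjusted p = 0.199) and 0.95 (adjusted p = 0.248).

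By limma, 0 of 11647 genes passed in untreated clones and 1806 had an unadjusted p below 0.05, where chance gives 582. Other ways of processing gave up to 19 calls, HLA-DRB1, CX3CR1, LOXL4, SESN3 and HLA-DRA among the 19 that passed after adding 64 to the linear signal, and leaving out untreated control replicate 2 gave 1 call, with the lone array assumed to vary like the other groups. On simulated data the test recovered 59 of 100 genes changed 2-fold and 97 of 100 changed 4-fold when all of these were changed at once. This does not show that a large change of a single gene would pass.

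By camera the FOXO target list was lower in untreated KO clones, in 21 of 28 members (median -0.24, 8 lower when adjusted over the list alone, adjusted p = 5.99e-05), with SESN3 at -1.27 and TP53INP1 at -0.60. The G2/M and mitosis list was higher in 30 of 33 members (median 0.36, 7 higher adjusted over the list alone, adjusted p = 6.8e-07), with the kinesin KIF2C at 0.74 and the proliferation antigen MKI67 at 0.69. The G1/S, cholesterol and autophagy lists were higher too (medians 0.20, 0.22 and 0.18, adjusted p = 0.0402 each), with MCM5 at 0.58, LSS at 0.64 and NPC1 at 0.55. With an estimated correlation all 5 calls were lost, with adjusted p = 0.767 for G1/S and 0.631 for the others, and fry called none. The other 14 lists did not pass, although 4 of 15 B cell identity genes were higher when adjusted over the list alone. The FOXO target median turns positive with scaling on the poly-A controls, those of the G1/S, cholesterol and autophagy lists turn negative with scaling on the hybridisation controls, and the G2/M median keeps its sign under both.

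After MK2206 the KO and control clones differed widely. The FOXO-induced gene DEPP1 was lower in treated KO than in treated control arrays (adjusted p = 0.00031), reading 2.23, below the filter, against 8.40, so that its difference of -6.17 rests on a signal that cannot be told from none. AKR1C3, an aldo-keto reductase (-5.20), RNASE6 (-4.32), PLAAT4 (-4.15), CCN2 (-4.13), FRMD3 (-4.08), FOXP2 (-3.98) and H2AC6 (-3.90) were the next lowest, with adjusted p between 0.00049 and 0.00747. The highest in KO clones were IMPA2 (6.35 ± 0.36), CDC45 (6.27 ± 0.33), HES6 (5.84), SHTN1 (5.71), UHRF1 (5.13), CHAF1B (4.71), MYCN (4.65) and ANKRD9 (4.52), with adjusted p between 0.000275 and 0.00215. In each, both KO arrays lay on one side of both control arrays. AKR1C3, RNASE6 and CCN2 lay below the filter in treated KO clones, and these highest genes except UHRF1 in treated control clones, so the size of their difference is set by dim values.

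**Figure D4:**
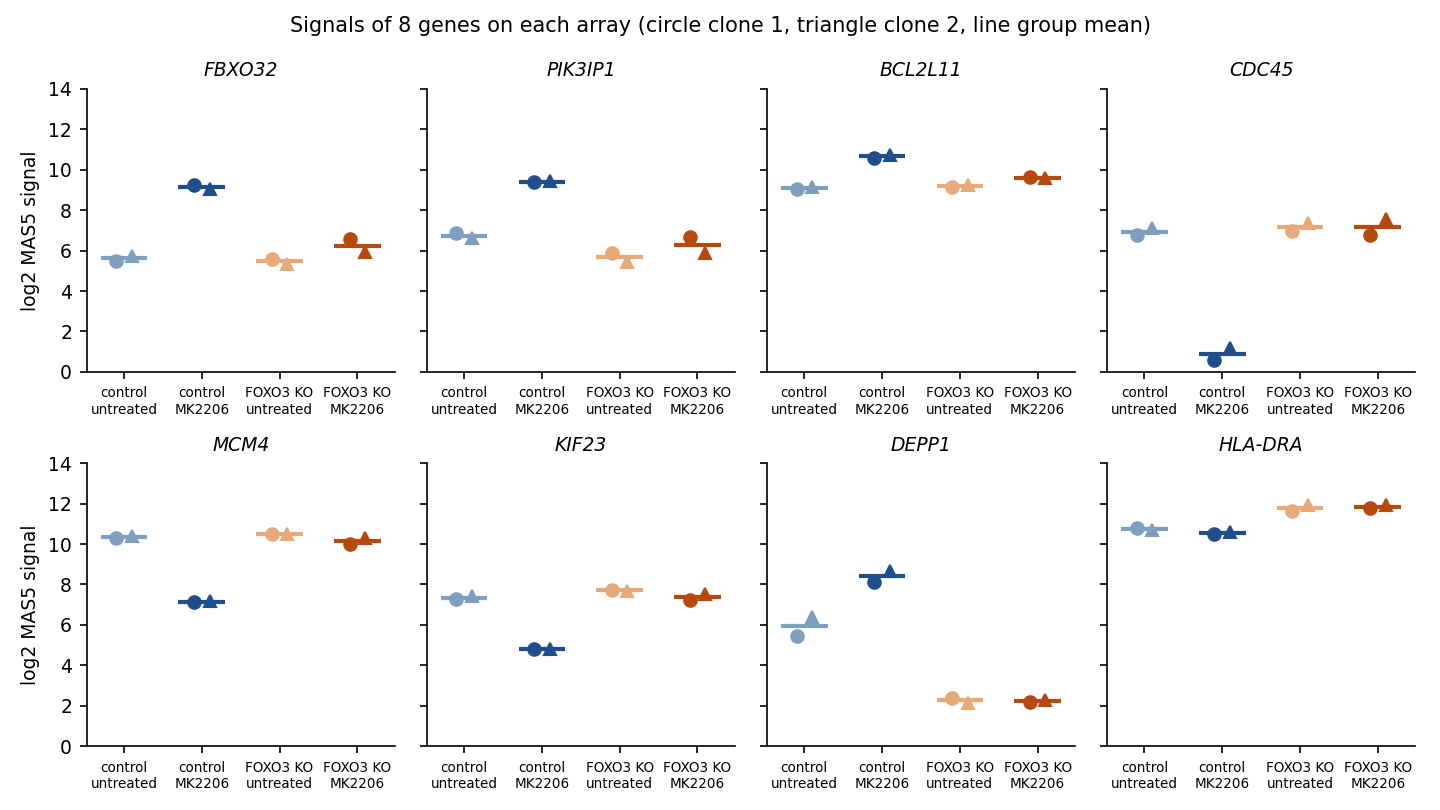
Log2 signal of 8 genes on each of the 8 arrays, with circles for clone 1, triangles for clone 2 and lines for the group means (n = 2). FBXO32, PIK3IP1 and BCL2L11 are highest and CDC45, MCM4 and KIF23 lowest in the treated control arrays, while DEPP1 reads between 2.14 and 2.38 in the 4 KO arrays and HLA-DRA lies higher in the KO than in the control arrays.

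Among treated arrays 31 of 32 G1/S and DNA replication genes (median 2.62) and 33 of 33 G2/M and mitosis genes (median 1.81) were higher in KO clones (31 and 33 adjusted over the list alone), among them MCM4 (3.01), TYMS (3.81) and KIF23 (2.57), and 22 of 28 FOXO targets were lower and 1 higher (24 and 1; median -1.62), among them TP53INP1 (-1.79) and PINK1 (-3.10). Their list tests gave adjusted p = 2.44e-16, 7.17e-16 and 1.18e-11, and adjusted p = 0.304, 0.304 and 0.188 with an estimated correlation. FOXO1 was also lower (-0.81, adjusted p = 0.0121), losing the call without treated control replicate 2 (adjusted p = 0.0523) or treated KO replicate 1 (adjusted p = 0.0556). Its difference turns positive with scaling on the poly-A controls.

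Higher in treated KO clones were also 16 of 28 ATF4 and amino acid genes with 2 lower (17 and 2 adjusted over the list alone), including PSAT1 (2.18) and the asparagine synthetase ASNS (1.10), 12 of 23 glycolysis genes with 2 lower (12 and 2), including PKM (2.83) and ENO2 (4.28), and 15 of 27 ribosome biogenesis genes (15 and 1 lower), including LYAR (1.81) and CAD (1.65). Lower were 11 of 23 growth factor and PI3K pathway genes with 2 higher (13 and 3), including RICTOR (-2.07) and the receptor IGF1R (-2.71), 6 of 13 immediate-early genes with 1 higher (7 and 1), including DUSP6 (-1.62), 5 of 24 ER chaperone genes with 2 higher (3 and 2), including ERN1 (-1.37), and 7 of 25 plasma cell genes with 5 higher (8 and 5), with CADM1 lower (-1.12) and the plasma cell surface marker SDC1 higher (1.32). These 7 lists had adjusted p between 0.00093 and 0.0481, and adjusted p between 0.188 and 0.476 with an estimated correlation, and fry did not call the ER chaperones (adjusted p = 0.0698). The medians of the growth factor, immediate-early and plasma cell lists, -0.52, -0.58 and -0.25, turn positive with scaling on the poly-A controls, and that of the ER chaperones, -0.11, under both control scalings.

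The other 9 lists did not pass among treated arrays. In the B cell identity list 5 of 15 members were higher and 3 lower (6 and 3 adjusted over the list alone), the class II genes HLA-DRA (1.31, adjusted p = 0.00148) and HLA-DPA1 (1.09, adjusted p = 0.00451) being higher and BACH2 lower (-1.89, adjusted p = 0.00149), while the list's median was positive and its mean and test negative (adjusted p = 0.769). EBP of the cholesterol list was higher (1.64, adjusted p = 0.00105). Of the 4 tested myeloid markers, FCER1G (1.18, adjusted p = 0.0173) and ITGAM (0.97, adjusted p = 0.0498) were higher in treated KO clones. FCER1G lost the call without treated KO replicate 1 or 2 (adjusted p = 0.0566 and 0.0761), and ITGAM without treated control replicate 2 (0.0967) or treated KO replicate 1 or 2 (0.131 and 0.149), and with the clone as a random block (0.0519).

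Among treated arrays 4359 genes passed, 2675 higher and 1684 lower in KO clones, against 5580 at an unadjusted p below 0.05. In all 4359 the arrays of the genotypes did not overlap, which such a call nearly requires (chance gives 33.3% for genes not chosen by their test). Higher genes made up 61.4% of the calls, 97.4% of 9048 with scaling on the poly-A controls and 72.4% of 3876 with scaling on the hybridisation controls. Without the filter on dim genes 2762 passed. Leaving out treated control replicate 1 left 2833 calls and leaving out treated KO replicate 2 left 2468, with the lone array assumed to vary like the other groups. This comparison shares its treated control arrays with that of MK2206 in control clones, so the overlap of their calls was not read as a separate result.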

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

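The tests of explanations and of other splits in this part were chosen after the result was seen, while the tests of the difference in response were not. What drew attention was a difference between the genotypes in their response to MK2206, tested as an interaction, and a signal in the control probe sets that the comparisons do not use. The difference in response passed for 1057 genes, and of the genes called over all 4 clones 96.4% of the rising and 98.2% of the falling ones responded less in FOXO3 KO clones. The median differences of the lists that passed were 2.36 for G1/S and DNA replication, 1.40 for G2/M and mitosis, 0.528 for glycolysis and hypoxia, 0.517 for ATF4 and amino acid response, 0.418 for ribosome biogenesis and MYC targets, -0.183 for autophagy and lysosome, -0.274 for NF-kB targets, -0.297 for ER chaperones, -0.375 for plasma cell identity, -0.431 for the growth factor receptor and PI3K pathway, -0.636 for immediate-early genes and -1.22 for FOXO targets. All 12 lost the call with an estimated correlation, with adjusted p between 0.233 and 0.415.

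Among named genes the difference was positive for CDC45 (6.02), IMPA2 (5.89), HES6 (5.47), SHTN1 (5.12), UHRF1 (4.93), MYCN (4.45), DTL (4.32), RRM2 (4.25), TYMS (3.39), MCM4 (2.86), ANLN (2.48), KIF23 (2.21) and PSAT1 (1.98). It was negative for CCN2 (-3.60), PLAAT4 (-3.22), H2AC6 (-3.18), PINK1 (-2.95), LOC101926984 (-2.88), PROX1 (-2.75), FBXO32 (-2.75), LRRC2 (-2.64), PIK3IP1 (-2.08), BACH2 (-2.01), RICTOR (-1.30), TP53INP1 (-1.19), BCL2L11 (-1.15) and FOXO1 (-1.04).

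Noisier KO arrays do not account for the near absence of a response in FOXO3 KO clones, since the median SD between clones of a KO group was at most 1.14 times that of a control group. The loss was not limited to the FOXO target list, since 97.4% of the 2384 called genes outside it also responded less. Whether the drug acted on the KO cultures cannot be told from these data. The KO clones' own changes had slopes of 0.138 and 0.0819 on the control response. The difference between the 2 KO clones under one treatment had slopes of 0.0978 and 0.154. That difference includes any lasting difference between the clones, which drops out of a clone's own change, so it is not a matched yardstick. Of the genes called as rising and as falling in control clones, 58.4% and 55.1% moved the same way in both KO clones. The opposite way was taken by 11.8% and 12.4%, which goes against an inactive drug. Genes that vary together do not count separately and only 2 KO clones were measured, so this stays open. A trait of the KO clones other than FOXO3 cannot be excluded with 2 clones per genotype, and clones from other guides, a FOXO3 add-back and the phosphorylation of AKT substrates in the same cultures would separate these explanations.

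The control transcripts added in the laboratory rose on the MK2206 arrays of control clones, the poly-A controls by 0.961 and 0.845 and the hybridisation controls by 0.349 and 0.634, against at most 0.190 and 0.214 in KO clones. A rise of the hybridisation controls, which enter after labelling, is what scaling each array to one mean could produce when the other signals on that array are weaker, and the smaller rise of 0.349 in control clones was above those in KO clones. Less messenger RNA per amount of RNA in treated control cells would raise the poly-A controls more than the hybridisation controls. That excess was 0.612 in control clone 1 and 0.211 in control clone 2, against -0.025 in KO clone 1 and 0.105 in KO clone 2. The pooled SD between clones of the poly-A minus the hybridisation level was 0.141. That SD includes any lasting difference between clones, which drops out of a clone's own change, so it is not a matched yardstick. With 2 clones per genotype this remains open. The amounts of control transcript added and the RNA yield per cell, not given in the sources used here, would settle it.

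The probe sets that name FOXO3 alone read lower in the group means of the KO clones under the deposited scaling, without reaching the level of absent signal. Loss of the part of chromosome 6 beyond FOXO3 is unlikely, since the 175 tested genes beyond it lay 0.0763 and 0.0447 above the 86 genes before it in KO clones 1 and 2 relative to control. Decay of an edited transcript could lower the signal of every probe set, but the site of the edit is not given in the sources used here and this was not tested. Sequencing of the edited site or the Western blot that the labels mention would answer it.

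The splits of the 8 arrays were too few for a test of chance. In the model of 4 groups, 2 of 18 splits within genotype, the real one included, called at least as many genes as the 2400 of the real one. The highest other count was 3091, in a split that parts the arrays of only 2 clones. Among the other splits that part the arrays of all 4 clones the highest count was 1489. The 6 splits that keep the treated and untreated arrays of the control clones apart, these among them, called between 1057 and 3091, and the 12 that mix them called 0, so the high counts of other splits follow the treatment of the control clones. In a model that ignores genotype the real split called 0, so all 35 splits into 4 and 4 arrays called at least as many and that count says nothing of chance, and the highest other count was 36, for the split by genotype.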

How the results depend on the processing

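Scaling on the poly-A or the hybridisation controls was added after the data were seen. The counts stayed within 1.5 times of the stated ones in 10 of 14 alternatives for MK2206 in control clones, 14 of 14 in FOXO3 KO clones, 8 of 13 over all clones, 6 of 13 for the difference in response, 6 of 13 for untreated KO against control and 10 of 13 for treated KO against control. All 22 alternative values of the share of called genes with a weaker response in KO clones kept their direction. They lay between 88.5% and 100% for rising and 92.8% and 99.6% for falling genes, each over the genes its own setting called. Of these values 8 come from fits without a whole clone. There the groups are unequal, so the averaged effect and the interaction are not independent and the choice of genes can itself move the share. On the poly-A controls the shares were 88.5% of 148 rising and 98.5% of 6935 falling genes, and on the hybridisation controls 94% of 281 and 98.8% of 3751. Both scalings shift every difference in response upward, which by itself raises the share for falling genes and lowers it for rising ones. The cause of a change was not tested unless stated. Apart from the changes given in the report, blocking on the clone altered no call of a named gene or a list, and the gene families were not run with it. A fit of only the groups compared was not run over all clones or for the interaction, since all arrays already enter. Of 59 list calls camera with an estimated correlation kept 0, and no list call was reversed. That alternative also rests on only 4 residual degrees of freedom, so the loss is not a measure of correlation alone. In control clones immediate-early genes and NF-kB targets lost the call with estimated correlations of -0.0183 and 0.00356, below the preset 0.01. Another probe set turned DUSP1 to -0.276 and PHLDA1 to 0.68 in control clones. Other probe sets of the called named genes lost the call in 14 of 30 values for the difference in response. They lost it in 7 of 65 in control clones, 4 of 27 over all clones and 3 of 36 for treated KO against control. Signals near the floor limit the size of large changes, and detection calls were not analysed here.

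Leaving out the filter on dim genes adds genes to adjust over and refits eBayes with them. The counts were then 2062 (control clones, 3696 with the filter), 730 (all clones, 2400), 34 (difference in response, 1057) and 2762 (treated KO against control, 4359). Requiring a 2-fold change as well left 1628, 440 and 1936 for control clones, all clones and treated KO against control, by its construction. Scaling on the poly-A controls gave 8065, 7083, 3608 and 9048, and untreated KO against control 4 in place of 0; scaling on the hybridisation controls gave 5599, 4032 and 1973, and 1. The clone as a random block gave 4366 over all clones and 2834 for the difference in response, and as a fixed block 2072. For the difference in response adding 64 gave 1774 and trend with robust 1699. For untreated KO against control centring gave 3, adding 64 gave 19, the 75th percentile filter 5, trend with robust 18 and all probe sets 1. Without 1 array, with the lone array assumed to vary like the other groups, counts ranged from 1906 to 2700 in control clones, 0 to 3 in KO clones, 0 to 1 for untreated and 2468 to 3679 for treated KO against control. Without 1 array or 1 clone they ranged from 164 to 1882 over all clones and 0 to 728 for the difference in response.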

Other observations

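The gene families and genes in this part, and the tests of them, were chosen after the values were seen, and the genes lie partly outside the rule for named genes. In control clones the signals of clustered histone genes, which normally yield transcripts during S phase, were higher with MK2206, while the replication genes fell. Which forms of histone transcript the labelling captured was not tested, so these signals do not show that histone expression in S phase rose. Of 15 tested histone genes 10 rose and 1 fell, with a median of 1.68 (camera adjusted p = 3.02e-06, or adjusted p = 0.116 with an estimated correlation), among them H2BC5 (2.59, adjusted p = 0.000376), H2BC12 (2.08) and H4C8 (1.98), while H4C11 fell (-1.81, adjusted p = 0.026). In FOXO3 KO clones none of the 15 passed (median 0.24), and the response differed with a median of -1.04 (adjusted p = 2.31e-06, or adjusted p = 0.112 with an estimated correlation). Cytoplasmic ribosomal proteins read 0.44 in the median in control clones, 13 of 58 rising and 3 falling, but this median turns negative under both control scalings, at -0.40 and -0.07.

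Several families of growing cells fell in control clones beyond the lists described above. Of 76 mitochondrial ribosomal proteins 34 fell and 1 rose (median -0.40), of 23 nucleoporins 13 fell (median -0.57), with NUP205 at -1.96 and NUP93 at -1.39, and of 33 proteasome subunits 14 fell (median -0.44). Of 13 LSM proteins, which bind RNA, 7 fell, LSM11 (-2.04) and LSM2 (-1.60) among them. Of 11 tubulins 7 fell, TUBB2A (-2.01) among them. Their camera tests gave adjusted p between 9.9e-07 and 0.00262, and adjusted p between 0.209 and 0.292 with an estimated correlation, and their medians stay negative under both control scalings. Among treated arrays 7 of 11 MHC class II genes were higher in KO than in control clones and 1 was lower (median 0.78, adjusted p = 0.0146, or adjusted p = 0.229 with an estimated correlation). Among untreated arrays none of the 11 passed, with a median of 0.36 (adjusted p = 0.000412, or adjusted p = 0.262 with an estimated correlation).

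Some genes moved in the KO clones in the direction seen in control clones. Of the 3696 genes called in control clones, 80 moved by more than 0.5 in that direction in both KO clones and 7 in the opposite one. Mean changes in KO and control clones were 1.46 and 1.61 for CDNF, 1.28 and 1.88 for CXCL10, 1.25 and 2.07 for ITGB8, 1.21 and 2.54 for PDE4B, 1.13 and 1.62 for STAT4, and -1.26 and -1.15 for LOXL4, none of them passing in KO clones (adjusted p = 0.765 or 1).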
